A study of Homo sapiens with 12 samples.

How the data were processed

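The study measured protein binding to DNA by ChIP-seq in HEK293 cells that stably expressed AZF, KLF3FD-AZF or KLF3FD, with an antibody to the V5 epitope tag carried by the constructs. Per the labels, each construct had 2 immunoprecipitation libraries and 2 input libraries, 12 in all. An input library is sequenced from chromatin before precipitation and serves as background. Groups and replicate numbers were taken from the sample titles. The labels of the 2 KLF3FD input libraries also name the V5 antibody, although title and description call them inputs, and they were grouped as inputs. The series text speaks of 4 cell lines, while the samples name 3 constructs with 2 replicates each. Per the submitters' processing notes, Trimmomatic 0.3.2, Bowtie2 2.2.1, SAMtools 0.1.18, HOMER 4.7.2 and DiffBind 1.10.2 were used, and the genome builds named were hg19 and GRCh37, which share the coordinates of the main chromosomes. Thresholds of peak calling were not stated.

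The authors deposited 3 peak lists and 1 table of differential sites. Per the file names, each peak list holds peaks that passed an irreproducible discovery rate (IDR) analysis, which keeps peaks ranked alike in the replicates, and gives 1 value per merged peak. The AZF and KLF3FD-AZF lists give a normalised tag count per peak, a coverage signal on a scale that the deposited files do not state. The KLF3FD list gives a peak score by the authors, also on an unstated scale. These values were used to rank, describe and filter peaks within their own list, and were not compared across lists. The smallest steps between them were compared, for the depth ratio of the lists, on the assumption that each step is 1 tag and that all lists were scaled to the same total. The differential table gives, per the file headers, a coverage signal for each of the 4 AZF and KLF3FD-AZF libraries, and the authors' log2 mean of each construct with their difference. The table headers name construct and replicate only, and were taken to be the immunoprecipitation libraries. The deposited log2 difference is AZF minus KLF3FD-AZF, and was turned so that positive values are higher in KLF3FD-AZF. All 4357 sites were at least 4-fold higher in KLF3FD-AZF. Another 51251 lines of the table were blank, and no p-value or FDR column was present, so the number of sites tested and the threshold are not known. Values per library were whole multiples of a fixed step to within 0.01 reads in 100% of sites (steps of 2.09 and 4.00 in AZF, 0.350 and 0.342 in KLF3FD-AZF), which gave read counts. Values of 1 read in AZF can stand for 0. Whether input reads had been subtracted was not checked, and if so such a value can also stand for more reads. In the peak lists the step was sought on the 60 lowest distinct values, with a tolerance equal to the rounding of the file (0.005 below 10 and 0.05 from 10). All levels were whole multiples in each list, where chance would give 14.5% in AZF, 43.0% in KLF3FD-AZF and 12.1% in KLF3FD.

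Overlap was counted with bedtools 2.31.1 at a minimum of 1 bp. As a measure of chance, peaks were moved along the chromosome 100 times in steps of 20 kb up to 1 Mb in either direction. A promoter peak had its centre within 1 kb of a TSS in the authors' distance column. Gene names were those of the nearest gene in the files, brought to current symbols through the RefSeq gene table of assembly GRCh38.p14, used for names and gene types only. Single peaks and sites are given under the name in the file, and members of gene lists under the current symbol. This matched 99.69%, 99.63% and 99.86% of the peaks of the AZF, KLF3FD-AZF and KLF3FD lists. Each peak was given to 1 gene, so a promoter shared by neighbouring genes counted for 1 of them. Shares are given with 95% Wilson intervals, which cover counting error only. Promoter shares and KLF3FD overlap were compared by two-sided Fisher exact tests with Benjamini-Hochberg adjustment over 8 tests. Of these, the 3 comparisons of promoter share among the zinc finger classes and that of KLF3FD overlap with shared peaks were set before the data were examined, and the others were added. The comparison within tag count deciles used the pooled Mantel-Haenszel odds ratio, and was also added after seeing the data.

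The 18 gene lists were the KLF family, the SP family, KLF3 corepressors and partners, reported KLF3 targets, the VEGF family and receptors, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, the proteasome, replication-dependent histones, zinc finger genes, olfactory receptors, keratins, HOX genes, globins, cholesterol synthesis, the cell cycle, heat shock genes and tRNA synthetases. For each list and each of 4 peak sets, the share of members with a promoter peak was compared with all other protein-coding genes by a two-sided Fisher exact test, adjusted over 72 tests. KLF3FD-AZF was compared with AZF in the same genes by an exact McNemar test, adjusted over 19 tests. Both tests treat genes as independent, which overstates the evidence for lists whose genes lie side by side. Lists taken by name pattern keep every gene that fits the pattern, such as PSMC3IP in the proteasome list.

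The text names, by a rule fixed before the data were examined, the 10 peaks of highest value in each of the AZF-only, shared, KLF3FD-AZF-only and KLF3FD classes on the numbered chromosomes and X (shared peaks by the KLF3FD-AZF tag count), the 15 differential sites of largest fold in each direction, and up to 4 members of each called gene list by value. VEGFA, KLF8, LGALS3 and KLF3 are always named. A few items that fall under the rule are not reported here. Other genes named, such as those of the dense bins and of the paired comparison, were chosen after their values were seen.

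The differential sites are reported as the authors gave them. As an added alternative, reads recovered from the steps were tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with adjusted p under 0.05 as the threshold, with and without a replicate block. Since the table holds only sites chosen for their fold, the number this test calls is not independent evidence. On simulated data of 4357 sites with 2 libraries per construct, it called 69% of sites changed 4-fold, 97% of sites changed 8-fold and 0.12% of unchanged sites. The simulation used 1 fixed spread between replicates, site means over both constructs, and mostly unchanged sites. In the data the median site held only 7 and 1 reads in AZF replicates 1 and 2, so these rates do not carry over to it. The overlap and odds ratio scripts were tested on simulated peaks and lists. Among 5000 simulated peaks, 100% of those built as shared were recovered. Lower counting bounds of a fold came from the 95% binomial interval of the pooled reads, taken as raw counts. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

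Alternatives set before the data were examined were reciprocal overlap of at least 50%, peak centres within 500 bp, the stronger 50% of each list by value, lists of equal length (only KLF3FD-AZF was shortened, to its 25322 strongest peaks), a promoter window of 5 kb, the authors' annotation column, leaving out peaks that overlap KLF3FD, stricter thresholds, a replicate block and leaving out each replicate. For the differential sites, thresholds and block could be applied only through the edgeR test on recovered reads, which was added after seeing the data. Sequence motifs were not analysed here, because the genome sequence was not used here. Input libraries were not analysed here.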

Results

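Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where an artificial zinc finger protein (AZF) bound the genome of HEK293 cells, an established human embryonic kidney line. The AZF was expressed alone, fused to the functional domain of the transcriptional repressor KLF3 (KLF3FD-AZF), or left out so that only the KLF3 domain, which has no zinc fingers of its own, was present (KLF3FD). Each construct was expressed stably and precipitated with an antibody to the V5 tag in 2 replicate cultures, each with an input control, which gave 12 libraries in 6 groups of 2. The comparisons asked whether the KLF3 domain changed where the artificial zinc finger bound. Every peak list merged 2 replicates, so the values within a list carry no replicate error. The p-values over peaks compare lists of peaks and not samples.

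The AZF list held 25322 peaks of 214 bp, the KLF3FD-AZF list 48003 peaks of 196 bp and the KLF3FD list 1439 peaks of 162 bp. Normalised tag counts ran from 19.9 to 243.5 in the AZF list (median 33.7) and from 8.39 to 153.7 in the KLF3FD-AZF list (median 26.6). Peak scores in the KLF3FD list ran from 4.45 to 21.3 (median 6.35). The 60 lowest distinct values of each list were whole multiples, to within rounding, of a fixed step, taken to be worth 1 tag, of 0.688 for AZF, 0.205 for KLF3FD-AZF and 0.0824 for KLF3FD. If the step is 1 tag and all 3 lists were scaled to the same total, which the files do not state, KLF3FD-AZF was sequenced 3.36 times and KLF3FD 8.34 times as deeply as AZF. The weakest listed peak then held 29 tags in AZF, 41 in KLF3FD-AZF and 54 in KLF3FD. Promoters, taken as positions within 1 kb of an annotated transcription start site (TSS), held 30.3% of AZF peaks (95% Wilson interval 29.7 to 30.8) and 30.9% of KLF3FD-AZF peaks (30.5 to 31.3). They held 10.8% of KLF3FD peaks (9.34 to 12.6).

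Most sites of the artificial zinc finger were also listed with the KLF3 domain added, along with many further sites. Of the AZF peaks, 20391 (80.5%, interval 80.0 to 81.0) overlapped a KLF3FD-AZF peak by at least 1 bp, and 4931 did not. The shared peaks made up 42.5% of the KLF3FD-AZF list (42.0 to 42.9), which left 27612 KLF3FD-AZF-only peaks. Moving the peaks along the chromosomes 100 times gave a mean of 405 overlaps and at most 580. With the KLF3FD-AZF list reduced to its 25322 strongest peaks, as many as AZF has, 58.7% of each list was shared.

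The promoter of VEGFA, which encodes a vascular growth factor, was occupied by both zinc finger constructs. The AZF list held 10 peaks nearest to VEGFA, and its strongest promoter peak lay at chromosome 6, 43737887 to 43738101 (hg19), with a tag count of 107.3. The KLF3FD-AZF list held 13 peaks nearest to VEGFA, with a promoter peak at 43737843 to 43738039 and a tag count of 98.6. Neither the KLF3FD list nor the differential sites held a peak at VEGFA. KLF3 itself and LGALS3, which encodes galectin-3, had a promoter peak in both zinc finger lists, with tag counts of 34.4 and 19.9 in AZF and 69.8 and 46.2 in KLF3FD-AZF. KLF8, a known KLF3 target, had a promoter peak of 9.41 in the KLF3FD-AZF list and no peak in the AZF list. That peak lay in the lowest tag count decile of its list (8.39 to 11.1), and no differential site lay nearest to KLF8. Its absence from the AZF list therefore does not show a difference between the constructs.

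The 10 strongest shared peaks lay almost all at promoters: 9 of them were within 1 kb of a TSS. They included SYDE2 (tag count 153.7 in KLF3FD-AZF), TIPIN (147.5), CIB2 (144.7), the cell cycle phosphatase CDKN3 (141.4), ZFP30 (138.9), RABEP1 (137.5), NFKBIB (137.5) and UBE3C (135.9), besides an intergenic peak nearest LINC00242 (140.6). The strongest AZF-only peaks, by AZF tag count, lay near H3F3AP4 (178.8), BAZ2A (178.1), HCFC1-AS1 (169.2), NBPF1 (140.3), LIN9 (139.6), RHOF (136.2), HNRNPL (133.4), HOXC-AS2 (132.1), LINC00893 (131.4) and MNT (129.3). The strongest KLF3FD-AZF-only peaks lay near SAMD11 (145.9), KANSL1-AS1 (135.3), CDC42BPA (116.6), H3F3AP4 (115.4), the growth factor receptor gene IGF1R (113.2), SMAD6 (112.5), CCDC88A (112.3), SUPT3H (110.5), JUND (110.3) and the heterochromatin protein gene CBX3 (110.3). Of these 10 KLF3FD-AZF-only peaks, 8 had the centre of an AZF peak within 500 bp without touching it, so that only the SAMD11 and IGF1R peaks stood clear of a listed AZF peak. Of the 10 AZF-only peaks, 3 (H3F3AP4, LIN9 and LINC00893) likewise had a KLF3FD-AZF centre within 500 bp. Of all KLF3FD-AZF-only peaks, 662 of the 8152 at promoters (8.12%) and 372 of the 19460 others (1.91%) had such a neighbour.

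Sites listed for AZF alone were the least promoter-bound of the zinc finger sites. Promoters held 20.1% of AZF-only peaks (19.0 to 21.3), 32.7% of shared peaks (32.1 to 33.4) and 29.5% of KLF3FD-AZF-only peaks (29.0 to 30.1). By two-sided Fisher exact tests, the promoter share of KLF3FD-AZF-only peaks exceeded that of AZF-only peaks (odds ratio 1.66, adjusted p = 9.5e-44 over 8 tests), as did that of shared peaks (1.93, adjusted p = 1.8e-70). Shared peaks exceeded KLF3FD-AZF-only peaks by 3.20 percentage points (odds ratio 1.16, adjusted p = 7.5e-14). That last direction turned when peaks of like height were compared. In all 10 tag count deciles of the KLF3FD-AZF list, KLF3FD-AZF-only peaks lay at promoters more often than shared peaks, with a pooled odds ratio of 3.50 (95% interval 3.31 to 3.69). In decile 6, promoters held 47.6% of the KLF3FD-AZF-only peaks and 11.5% of the shared peaks, and in decile 10 they held 79.0% and 72.5%. With a promoter window of 5 kb, the order of KLF3FD-AZF-only and AZF-only peaks also turned (38.5% and 40.9%, odds ratio 0.904). Against AZF-only peaks, the odds ratios rose to 11.1 for KLF3FD-AZF-only and 5.80 for shared peaks with lists of equal length. That cut keeps the strongest KLF3FD-AZF peaks, which lay at promoters more often. It also raised the AZF-only peaks to 10470, with 11.7% at promoters, so the rise comes in part from the cut itself. With classes drawn from peak centres within 500 bp the odds ratios were 3.07 and 4.07, and that for shared peaks was 1.19 with the 5 kb window.

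**Figure D1:**
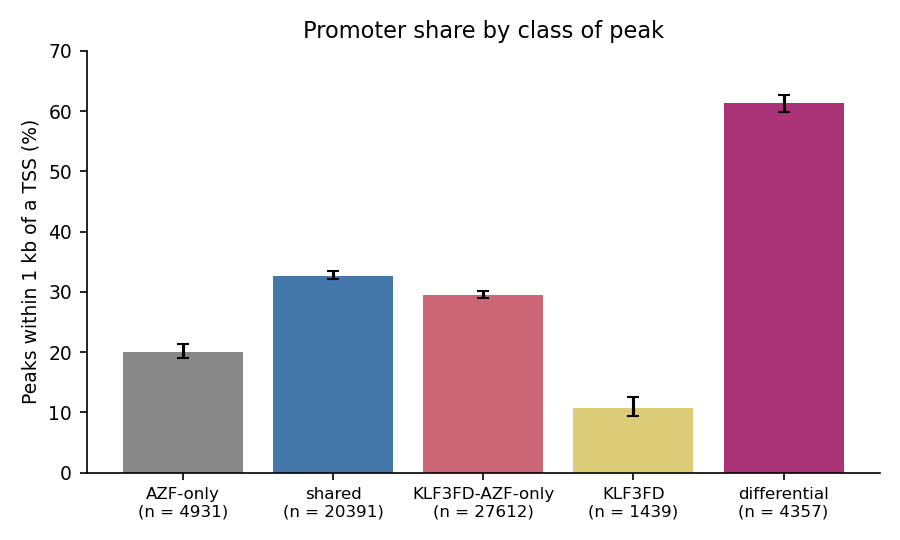
Share of peaks within 1 kb of a TSS, in percent, for AZF-only, shared, KLF3FD-AZF-only and KLF3FD peaks and for the differential sites of the authors, with 95% Wilson intervals as error bars and the number of peaks under each bar. The share ran from 10.8% in KLF3FD peaks to 61.3% in the differential sites.

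**Figure D2:**
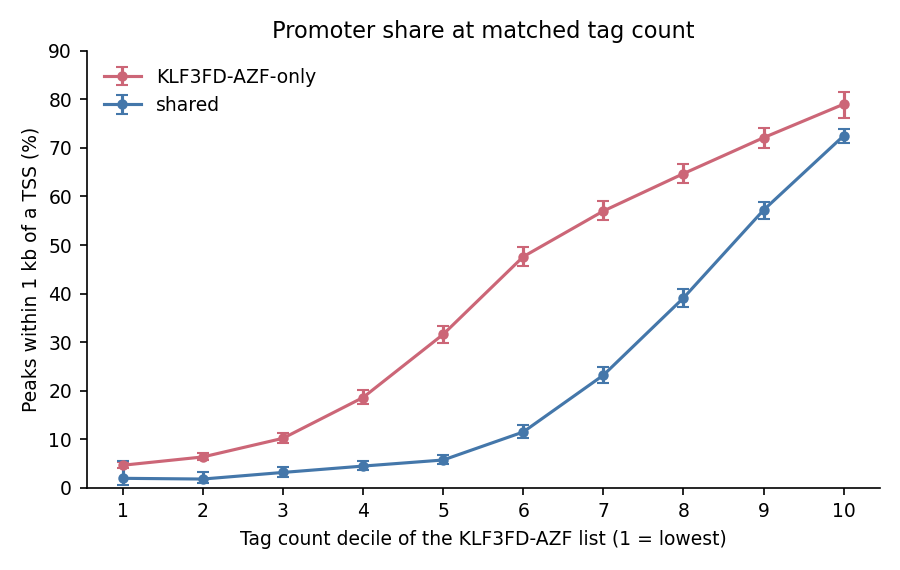
Share of peaks within 1 kb of a TSS, in percent, by tag count decile of the KLF3FD-AZF list, for KLF3FD-AZF-only peaks and for peaks shared with AZF, with 95% Wilson intervals. KLF3FD-AZF-only peaks lay above shared peaks in all 10 deciles.

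The KLF3 domain without zinc fingers gave few peaks, mostly away from promoters and mostly at other places than the zinc finger constructs. Of the 1439 KLF3FD peaks, 264 (18.3%, interval 16.4 to 20.4) overlapped a KLF3FD-AZF peak and 79 (5.49%, 4.43 to 6.79) an AZF peak, against means of 9.66 and 5.67 after moving the peaks. Promoters held 35.2% of the KLF3FD peaks that overlapped KLF3FD-AZF and 5.36% of the others (odds ratio 9.60, adjusted p = 4.6e-35, Fisher exact test). The KLF3FD-AZF list itself had 30.9% of its peaks at promoters. Peaks chosen for overlap with it take on much of that share, so the odds ratio is in part set by the choice. The strongest KLF3FD peaks included those near LOC101927683 (score 21.3), PCNXL2 (19.4), CYP2B7P (19.0), SH3GLB1 (18.3), SAMD11 (18.2), BMPER (17.4), MIR4503 (17.3), EFNA5 (16.7) and TES (16.5), none of these at a promoter. The SAMD11 peak, in an intron at chromosome 1, 877239 to 877401, lay inside the strongest KLF3FD-AZF-only peak, at 877227 to 877423. KLF3FD overlap was more frequent among KLF3FD-AZF-only peaks (193 of 27612, 0.699%) than among shared peaks (71 of 20391, 0.348%), with an odds ratio of 2.01 (adjusted p = 1.8e-07). It was 2.95 with reciprocal overlap, 1.79 with peak centres within 500 bp, 2.06 with the stronger 50% of each list and, in a comparison added after seeing the data, 5.70 within tag count deciles. Among AZF-only peaks, 3 overlapped a KLF3FD peak.

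The differential table of the authors listed 4357 sites, and at every site in it both KLF3FD-AZF libraries lay above both AZF libraries. For a single site, chance alone gives this order in 16.7% of cases with 2 libraries against 2, but the table holds only sites chosen as higher in KLF3FD-AZF, which largely fixes the order. The fold ran from 4 to 60.6 with a median of 5.92, and no site was lower in KLF3FD-AZF. Of the 15 sites with the largest fold, 10 lay within 1 kb of a TSS. The largest, at ZNF48, had 185 ± 26.3 scaled reads in KLF3FD-AZF and 3.05 ± 1.35 in AZF (mean ± SD, n = 2 each), a fold of 60.6 with a lower 95% counting bound of 18.6. ZNF354A (fold 52.3), the deubiquitinase gene USP5 (51.8), RAB29 (47.3), ZNF768 (46.9), ZNF3 (46.8), RNFT2 (45.6), ELF2 (44.4), TRIP12 (44.0) and the survival factor gene MCL1 (43.1) followed within 1 kb of their TSS. PSD (57.6), NFIX (48.7), SNORA59A (48.6) and MCC (42.2) had such sites farther from the TSS. At SAMD11, a site at chromosome 1, 875693 to 875895, had 571 ± 94.0 scaled reads in KLF3FD-AZF and 11.4 ± 10.5 in AZF, a fold of 50.1. At 13 of these 15 sites each AZF library was at 1 read, the lowest value in the table. That value can stand for none, or for more reads if input had been subtracted. The counting bound gives only the lower side, and holds only if these are raw reads.

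**Figure D3:**
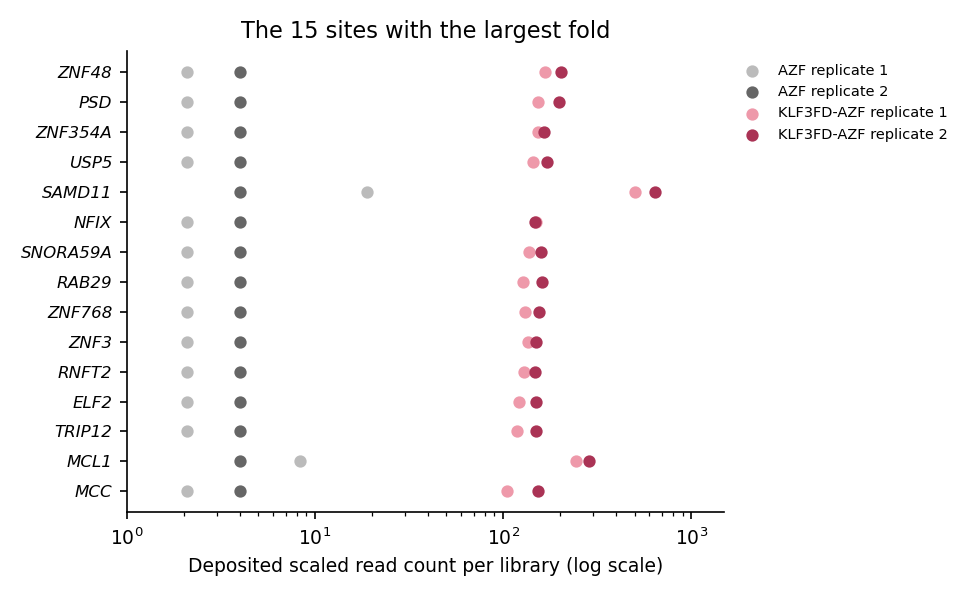
Deposited scaled read counts (log axis) in each of the 4 libraries at the 15 differential sites with the largest fold, named by nearest gene. The KLF3FD-AZF libraries lay above the AZF libraries at all 15 sites.

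The AZF libraries had few reads at these sites. In the scaling of the authors 1 read was worth 2.09 in AZF replicate 1 and 0.350 in KLF3FD-AZF replicate 1, so the gap in reads goes in part with the library factors and in part with the choice of sites lower in AZF. The sites held 54070 and 17598 reads in AZF replicates 1 and 2, and 1501971 and 1717317 in KLF3FD-AZF replicates 1 and 2. AZF was at 1 read in both libraries at 945 sites (21.7%). The log2 ratio of the replicates had an SD of 1.58 in AZF and 0.36 in KLF3FD-AZF across sites. The lower counting bound of the fold was above 2 at 3761 sites (86.3%). The sites were chosen as higher in KLF3FD-AZF from these same reads, and the bound leaves out the spread between replicates. This count is therefore not independent evidence for the folds.

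Most of the differential sites lay at promoters. Promoters held 61.3% of them (59.8 to 62.7), and the median distance to a TSS was 428 bp. Of the 4357 sites, 3931 (90.2%, interval 89.3 to 91.1) overlapped a KLF3FD-AZF peak, 336 (7.71%, 6.96 to 8.54) an AZF peak and 122 (2.80%, 2.35 to 3.33) a KLF3FD peak. KLF3FD-AZF peaks at differential sites lay at promoters more often than the other KLF3FD-AZF peaks (61.9% and 28.1%, odds ratio 4.15). They overlapped a KLF3FD peak in 2.80% of cases, against 0.349% of the others (odds ratio 8.21, adjusted p = 1.5e-49, Fisher exact test). Neither comparison was matched for tag count, with which the promoter share of KLF3FD-AZF peaks rose. How far peak height accounts for these differences was not tested. Among the sites with 1 read in both AZF libraries the promoter share was 33.7%, and among the others it was 69.0%.

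At the level of genes, KLF3FD-AZF had more promoters with a listed peak than AZF in each of the 18 gene lists. The excess passed the test in 6 of them. By the step sizes, KLF3FD-AZF may have been sequenced 3.36 times as deeply as AZF. Greater depth alone could list more promoters, and lists of equal length do not remove a difference in depth, so depth stays open as a cause. Of 20052 protein-coding genes, 6047 (30.2%) had a promoter peak in AZF, 10492 (52.3%) in KLF3FD-AZF, 133 (0.663%) in KLF3FD and 2315 (11.5%) among the differential sites. A promoter peak in KLF3FD-AZF but not in AZF was found for 4635 genes, and the reverse for 190. With the KLF3FD-AZF list reduced to its 25322 strongest peaks, these counts were 3527 and 336. By exact McNemar tests over 19 comparisons, the excess of KLF3FD-AZF held for zinc finger genes (146 against 3 genes, adjusted p = 1.5e-38), cytosolic ribosomal proteins (23 against 1, 1.9e-05), respiratory chain genes (14 against 0, 4.6e-04), tRNA synthetases (14 against 0, 4.6e-04), the cell cycle list (12 against 1, 0.0108) and the proteasome (11 against 1, 0.0172). All protein-coding genes together showed the same excess (4635 against 190), so these calls do not show that the 6 lists differ from other genes. Lists with few such genes could hardly pass, as for the SP family (4 against 0, adjusted p = 0.158, McNemar test). The cell cycle genes with a promoter peak in KLF3FD-AZF alone included CCNA2, CCNE1, CDK1, MYC and RB1. With lists of equal length, the calls for zinc finger genes, ribosomal proteins and tRNA synthetases held, and those for respiratory chain genes (adjusted p = 0.0711), the cell cycle list (0.0711) and the proteasome (0.191) were lost. There, KLF3FD-AZF was no longer ahead for olfactory receptors (0 against 1 gene) and reported KLF3 targets (0 against 0). With a promoter window of 5 kb all 6 calls held, and histones (9 against 0, adjusted p = 0.0105) and keratins (7 against 0, 0.0330) were gained.

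More KLF3FD-AZF promoters than in other genes were found in 4 lists, among which the KLF family was not (13 of 17, adjusted p = 0.147). All 9 SP family genes had a KLF3FD-AZF promoter peak (adjusted p = 0.0216, Fisher exact test with Benjamini-Hochberg adjustment over 72 tests), led by SP4 (tag count 86.6), SP1 (83.9), SP3 (70.6) and SP9 (67.3). Of the 12 KLF3 corepressors and partners, 11 had such a peak (adjusted p = 0.0334), led by EHMT2 (108.7), HDAC1 (93.9), CTBP2 (82.7) and RCOR1 (77.8). So did 24 of 28 cell cycle genes (adjusted p = 0.00327), led by CDK6 (111.3), CDKN1B (108.3), CDK4 (107.6) and E2F2 (93.7), and 284 of 477 zinc finger genes (adjusted p = 0.0103), led by ZNF398 (103.1), ZNF34 (102.1), ZNF839 (98.6) and ZNF574 (98.4). Fewer KLF3FD-AZF promoters than in other genes were found among replication-dependent histones (8 of 71, adjusted p = 7.6e-12, led by H1-3 and H1-2), olfactory receptors (5 of 390, adjusted p = 5.2e-115, led by OR1E1), keratins (5 of 55, adjusted p = 2.6e-10, led by KRT18 and KRT8) and globins (HBQ1 alone, 1 of 10, adjusted p = 0.0372). Many histone, keratin, globin, olfactory receptor and zinc finger genes lie side by side, while the test treats them as independent. Their p-values therefore overstate the evidence. With a promoter window of 5 kb, the calls for zinc finger genes (adjusted p = 0.257), corepressors (0.0606) and globins (0.479) were lost, and that for globins was also lost with lists of equal length (0.0828).

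In the AZF list, heat shock genes had more promoter peaks than other genes (21 of 43, adjusted p = 0.0439), led by HSPD1 (tag count 160.3), HSPA14 (121.7), HSPA1A (114.2) and HSPA1B (109.4), a call that was lost with the 5 kb window (adjusted p = 0.189). Fewer were found among cytosolic ribosomal proteins (13 of 87, adjusted p = 0.0103, led by RPL10A at 112.8), histones (H1-3 and H4C2, 2 of 71, adjusted p = 6.4e-08), keratins (KRT18, KRT17, KRT80 and KRT8, 4 of 55, adjusted p = 4.7e-04) and olfactory receptors (OR10S1 alone, 1 of 390, adjusted p = 3.2e-58). The KLF3FD list stood out only for HOX genes, the developmental regulators of body axis identity. Of these, 7 of 39 had a promoter peak against 0.630% of other genes (odds ratio 34.5, adjusted p = 6.4e-08, Fisher exact test). The strongest were at HOXA9 (score 10.3), HOXA4 (9.48), HOXB4 (8.65) and HOXA5 (7.58). HOX genes lie side by side in clusters, while the test treats them as independent, so this p-value overstates the evidence.

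Differential sites lay at the promoters of 6 of 17 KLF genes (adjusted p = 0.0377), with folds of 15.7 at KLF12, 14.1 at KLF6, 8.10 at KLF11 and 7.82 at KLF5. They lay at 4 of 9 SP genes (adjusted p = 0.0498), with folds of 8.41 at SP9, 7.35 at SP3, 4.25 at SP4 and 4.03 at SP7. They also lay at 5 of 12 corepressors and partners (adjusted p = 0.0362), with folds of 24.5 at WIZ, 10.2 at RCOR1, 5.18 at CTBP1 and 4.68 at KDM1A. Of the cell cycle list, 9 of 28 genes had such a site (adjusted p = 0.0177), with folds of 39.6 at CCNE1, 8.52 at MYC, 7.80 at CCNE2 and 6.96 at E2F3. At KLF5, SP7, WIZ and CCNE1 both AZF libraries were at 1 read (3.05 ± 1.35 scaled reads), which can stand for none, so these folds are not exact. Histones (H4C1 alone, 1 of 71, adjusted p = 0.0156) and olfactory receptors (0 of 390, adjusted p = 5.0e-20) had fewer. Zinc finger genes as a list had no excess (55 of 477, odds ratio 0.999, adjusted p = 1.00). The KLF call was lost with the 5 kb window (adjusted p = 0.0542), where its odds ratio was 3.74, against 4.19 with 1 kb. Against the genes with a KLF3FD-AZF promoter peak as background, a choice made after the data were seen, none of the 6 calls held, with adjusted p = 0.160 for KLF, 0.312 for SP, 0.216 for the corepressors and 0.415 for the cell cycle list.

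The other lists did not pass the test in any of the 4 peak sets, though with lists of equal length tRNA synthetases gained a KLF3FD-AZF call (odds ratio 2.70, adjusted p = 0.0340). In AZF and KLF3FD-AZF, promoter peaks were found at 3 and 4 of 5 reported KLF3 targets, 5 and 7 of 10 genes of the VEGF family and receptors, 30 and 44 of 96 respiratory chain genes, 10 and 20 of 40 proteasome genes, 8 and 13 of 18 cholesterol synthesis genes, and 10 and 24 of 33 tRNA synthetases. With only the genes named in any list as background, also chosen after the data were seen, 14 of the 20 calls over all sets were lost, among them the SP, corepressor, cell cycle and heat shock calls (adjusted p = 0.399, 0.535 and 0.321 in KLF3FD-AZF and 0.264 in AZF). The HOX call in KLF3FD held under each alternative run on it, though each of these also treated the clustered HOX genes as independent.

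**Figure D4:**
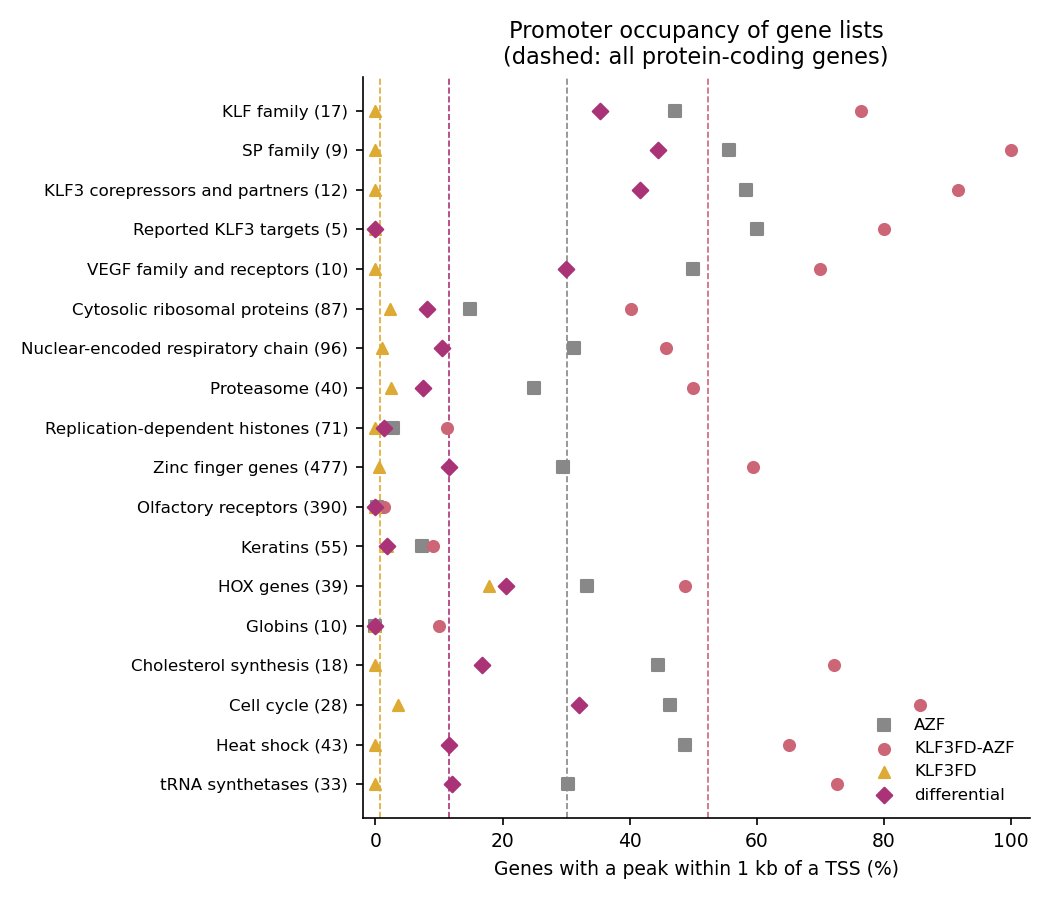
Share of the genes of each list, in percent, with a peak within 1 kb of a TSS in the AZF, KLF3FD-AZF and KLF3FD lists and among the differential sites, with the number of genes in brackets and the share among all protein-coding genes as dashed lines. HOX genes lay far to the right of the KLF3FD line of 0.663%, and olfactory receptors lay near 0 in all 4 peak sets.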

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

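The comparisons within tag count deciles, by gene backgrounds, by edgeR and by another depth ratio were chosen after seeing the data, as were promoter classes by peak centres and differential sites with more than 1 AZF read; the other alternatives were set before the data were examined. Each single gene list call was counted once for every alternative run on it. Of these cases, 62 kept direction and call and 29 kept direction but lost the call. With a reciprocal overlap of 50%, 78.4% of AZF and 41.4% of KLF3FD-AZF peaks were shared, and 10.8% and 1.95% of KLF3FD peaks overlapped KLF3FD-AZF and AZF. With centres within 500 bp these shares were 83.8%, 44.6%, 26.0% and 8.27%, and differential sites met AZF, KLF3FD-AZF and KLF3FD peaks in 15.1%, 93.2% and 3.58% of cases. With the stronger 50% of each list they were 81.8%, 43.2% and, for KLF3FD with KLF3FD-AZF, 13.9%. With KLF3FD-AZF alone shortened, to 25322 peaks, 58.7% of both lists was shared. Differential sites with more than 1 read in an AZF library overlapped AZF in 9.85% and KLF3FD-AZF in 92.3% of cases. The promoter odds ratio of KLF3FD-AZF-only against AZF-only peaks reversed to 0.904 with a 5 kb window. There and with the authors' annotation the cause was not tested. That of shared against KLF3FD-AZF-only peaks was 1.01 with the authors' annotation and reversed to 0.524 with lists of equal length and to 0.286 within tag count deciles; in the pooled comparison, weak KLF3FD-AZF-only peaks, few of them at promoters, lower the share. The number of gene lists with more AZF promoters moved from 1 to 2 with the 5 kb window, where heat shock lost its call (adjusted p = 0.189) and the KLF family (0.0457) and HOX genes (0.0378) gained one. Calls were also gained by the KLF family in KLF3FD-AZF and HOX genes at differential sites (5 kb, both 0.0494) and by tRNA synthetases in KLF3FD-AZF (equal length, 0.0340), and in the paired comparison by histones (0.0105) and keratins (0.0330) with 5 kb. Against the genes named in any list, the lists with more AZF promoters fell to 0, with fewer to 2, with more KLF3FD-AZF promoters to 1, with fewer to 2, and those with more or fewer differential promoters to 0 and 0, as they did (0 and 0) against the genes with a KLF3FD-AZF promoter peak. Leaving out each library in turn left between 3157 and 4189 of the 4357 differential sites at least 4-fold higher. With edgeR on the recovered reads, 4357 sites were called with no block and 4355 with the replicate block. The deviations of same-numbered libraries correlated by -0.08 across sites. AZF replicates 1 and 2 were at 1 read in 28.2% and 50.1% of sites, which weakens any such correlation. The correlation therefore cannot tell whether the numbers pair the samples. Leaving out a library in edgeR gave 2505 to 4357 calls, with 2867 without KLF3FD-AZF replicate 1 and 2505 without KLF3FD-AZF replicate 2, a lone library being assumed to vary like the other construct. The planned motif alternatives were not run, and the planned FDR thresholds could be applied only to recovered reads (4356 sites at 0.01, and 3987 at 0.05 with at least 4-fold).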

Other observations

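The tests of read depth, antibody background, library factors and counting error given here were chosen after the results were seen. Those of peak centres and of DNA copies were written down before their values were computed.

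Part of the KLF3FD peaks lay in dense bins. Bins of 1 Mb with at least 5 KLF3FD peaks numbered 20 and held 138 of the 1439 peaks (9.59%), while 1000 draws of 1439 peaks from the KLF3FD-AZF list gave a mean of 86.2 and at most 148 peaks in such bins, with 138 or more in 5 of the draws. The densest bins lay on chromosome 5 next to ZNF608 (13 and 9 peaks), on chromosome 6 next to FOXC1 (11), on chromosome 7 around the HOXA cluster (10, of which 8 lay nearest a HOXA or HOXA antisense gene) and on chromosome 8 next to ZNF703 (10). Others lay at AUTS2 (7), ARID5B (6), NRP1 (5) and around the HOXC cluster (5). In all, 19 KLF3FD peaks lay nearest to a HOX gene or HOX antisense gene, on 4 chromosomes, and 6 of them overlapped a KLF3FD-AZF peak and 4 an AZF peak. By contrast, chromosomes 16, 19 and 22 held 0.764%, 0.973% and 0.208% of KLF3FD peaks, against 4.27%, 5.90% and 3.08% of KLF3FD-AZF peaks.

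KLF3FD peaks lay at the promoters of 2 of 87 ribosomal protein genes (2.30%, adjusted p = 0.273) and 1 of 40 proteasome genes (2.50%, adjusted p = 0.411), against 0.663% of all genes. They were RPL37 (score 8.49), RPS7 (7.58) and PSMD3 (5.19), and the PSMD3 promoter also held a differential site with a log2 fold of 2.64. The cell cycle list had 1 KLF3FD promoter peak, at RBL1 (score 8.0), which both zinc finger constructs also occupied, with tag counts of 107.3 in AZF and 89.4 in KLF3FD-AZF.

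At equal tag count, KLF3FD-AZF-only peaks lay at promoters more often than peaks shared with AZF. The pooled odds ratio within tag count deciles, 3.50 (3.31 to 3.69), is this pattern itself and cannot tell whether lower depth of the AZF libraries caused it, so depth stays open. Summits set apart by up to 500 bp in wide promoter signals were argued against by classes drawn from centres within 500 bp. These gave 3.39 (3.21 to 3.58), higher in all 10 deciles. Summits farther apart in the same promoter were not reached by this rule and stay open. Background of the antibody or of open chromatin would give peaks at the same promoters without zinc fingers, and 0.761% (0.594 to 0.974) of the KLF3FD-AZF-only promoter peaks overlapped a KLF3FD peak. The KLF3FD list held only 156 promoter peaks and could have reached at most 1.91% of these 8152 peaks, so this value cannot tell and background stays open. Another candidate explanation that stays open is that the KLF3 domain adds binding at promoters, and a higher level of the fusion protein, not measured here, could do the same.

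All listed differential sites were higher in KLF3FD-AZF. With the depth ratio of the merged lists in place of the authors' library factors, 100% of sites stayed at least 4-fold higher, with a median log2 fold of 3.79. That ratio raises the folds, so this value cannot tell whether the factors are too favourable to KLF3FD-AZF, and they stay open as a cause. Counting error was tested by asking how few AZF reads no change would allow, with Bonferroni correction over all 55608 lines of the table. At 82.4% of sites (3591) the AZF reads were fewer than that. The sites were chosen from these same reads as lower in AZF, and the number of sites tested is not known. The expected reads also rest on the authors' library factors, so this value cannot tell and counting error stays open. A more efficient precipitation of KLF3FD-AZF, or a variation between cultures larger than 2 replicates show, may also contribute and was not tested.

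The dense KLF3FD bins could reflect extra DNA copies, which would raise the peaks of every construct there. Distal AZF peaks in these bins had a median tag count of 37.8, against 31.0 elsewhere, a ratio of 1.22, above 99.7% of 1000 random sets of bins, whose central 95% ran from 0.910 to 1.13. In KLF3FD-AZF the ratio was 1.31. The ratio lies between the values set in advance for and against extra copies, so these cannot be told apart from a local preference of the KLF3 domain. Clusters of open chromatin were not tested.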
